A study of Drosophila melanogaster with 6 samples.

How the data were processed

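Total RNA from 6 samples of whole adult flies, each of 25 males and 25 females, was hybridised after biotin labelling of 2 ug of RNA to Affymetrix Drosophila Genome 2.0 arrays, per the labels' protocols. The array covers each transcript with probe sets of short oligonucleotides. Groups were taken from the sample titles: 3 samples of the cross of da-GAL4 to the UAS peptide line and 3 samples of the uncrossed UAS line. The labels do not say whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

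The values used were the probe set intensities of the deposited series table, on a linear scale with 1 decimal. The software that summarised the probes, its background correction and its scaling are not given in the sources used here. In the values, the mean without the top and bottom 2% of signals was 2500.1 on each of the 6 arrays, so the arrays share a scale that the authors set before deposit. Scanner files and detection calls were not used here. All 6 value columns were used.

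The table held 18952 probe sets. The 183 Affymetrix control probe sets were left out of the tests, which leaves 18769. By the platform annotation, 13647 probe sets had 1 gene symbol, 402 had several and 4720 were not listed or had none. Of the first kind, 13544 matched the gene table of the Release 6 assembly, which was used for current names and for gene order only, and 103 did not and kept the annotation's symbol. Genes are named only from probe sets with 1 symbol. Of 11983 genes, 1094 had more than 1 such probe set, and the one with the highest mean log2 signal over all 6 arrays stood for the gene.

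Signals were converted to log2(signal + 1), and fold changes are on that scale, which understates changes of low signals. Differences, cross minus control, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior), 2-sided, with Benjamini-Hochberg adjustment over all tested probe sets. This fit, the gene lists, the rule for named genes and most other settings were fixed before the data were examined. The other settings fixed beforehand were quantile scaling, median centring, a pseudocount of 16, leaving out the dimmest 33.3% of probe sets, a trended and robust prior, the replicate number as a block, leaving out each array, a test with unequal group variances for each probe set, a 2-fold minimum, leaving out probe sets that can read several transcripts, averaging the probe sets of a gene, and an estimated correlation in the set tests. The count of the trended fit under its own alternatives was added after seeing the data. As a guide to background, the 95th percentile of 27 control probe sets for Bacillus genes was taken on each array. It lay at 108 ± 15.4 in the control and 110 ± 14.7 in the cross (SD, n = 3 each), and 9.82% of probe sets were at or below it on all arrays. Where a gene lay at or below it on every array of one group, its fold is given as a bound against it, and where both groups did, no fold is given.

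The 20 gene lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera with an estimated correlation, and with fry. With the preset correlation 4 lists passed an adjusted p of 0.05 and with the estimated correlation 0, the smallest adjusted p being 0.783. In simulated data with 1 list, that of digestive enzymes, shifted by -1 on the log2 scale, 2 lists passed with the preset correlation. A list that was not shifted was thus also called. With fry, 0 lists passed for a shift in 1 direction after adjustment and 9 for changes in either direction. The 9 were the lists of antimicrobial peptides, other immune-induced peptides, immune recognition and signalling, and glutathione S-transferases. The lists of cytochrome P450 genes, heat shock, digestive enzymes, odorant-binding proteins, and stress and insulin signalling were the others. Members past the test are given over all genes and adjusted over the list alone.

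By the rule for named genes, the 12 largest rises and 12 largest falls among genes past the test with groups apart were to be named, or, with none past it, the 6 genes with the smallest p in each direction. No gene passed, so these 6 were named as not passing, together with all measured antimicrobial peptide genes, up to 2 genes of each other list with the smallest p, and da. The w gene, which the rule also lists, is not reported here. The same rule was then run on the trended fit. Those names, and GNBP2, Jon44E, Ser12, GstO2 and RFeSP, were chosen after their values were seen.

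The fits were tested on simulated data with the means of the real probe sets and their SDs as moderated by the fixed fit. In these, 200 of 18769 probe sets were changed by known factors. Noise was drawn independently for each probe set, so structure shared between probe sets was not simulated. The counts of false calls need not hold for the real arrays. For this comparison, the fixed fit recovered 0 of 50 probe sets changed 1.5-fold, 2 of 50 changed 2-fold, 34 of 50 changed 4-fold and 39 of 50 changed 8-fold, with 8 calls among the 18569 unchanged ones. The trended fit recovered 0, 12, 36 and 41 of 50, with 5 such calls. The fit without the dimmest 33.3% recovered 2, 14, 34 and 34 of 50, with 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.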

Results

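Whole adult flies of Drosophila melanogaster that carried a driver and an antimicrobial peptide transgene were compared with flies that carried the transgene alone. In the cross, da-GAL4, a driver that takes the promoter of the widely expressed gene daughterless (da), switches on a UAS transgene for an antimicrobial peptide in most tissues. The control was the UAS stock without the driver. Antimicrobial peptides are small secreted proteins of the humoral immune response that kill bacteria and fungi, and the title of the series places the experiment in a study of tolerance to oxidant stress. Each group had 3 samples of 25 males and 25 females, and each sample was hybridised to 1 Affymetrix Drosophila Genome 2.0 array. The labels do not name the peptide. A total of 18769 probe sets were tested, and 11983 genes had a probe set annotated to that gene alone. Median signals were 858 ± 9.62 in the control arrays and 831 ± 68.1 in the arrays of the cross (SD, n = 3 each). Correlations of log2 signals across probe sets were 0.946 to 0.958 within groups and 0.945 to 0.953 between groups. The number of arrays, 6, limited the precision.

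The comparison asked which transcripts differed between the cross, with driven expression of the peptide, and the uncrossed line. The cross also carried the driver and chromosomes of the driver stock, and no driver-only flies were analysed here. Differences below are thus those of the cross as a whole, not of the peptide alone. The gene with the smallest p among higher genes was CG17751, with a signal of 1934 ± 118 in the control and 7993 ± 865 in the cross, 4.12-fold apart. Arc1, a homologue of the neuronal Arc gene that encodes a capsid-forming protein, had signals of 11900 ± 1169 and 41730 ± 4075, 3.51-fold apart. The drosomycin-like peptide gene Drsl4 had signals of 3479 ± 1758 and 20700 ± 2446, 6.47-fold apart. On the lower side, CG6283 had signals of 3045 ± 298 in the control and 427 ± 117 in the cross, 7.29-fold apart, and CG7900 had signals of 2811 ± 341 and 776 ± 101, 3.62-fold apart (SD, n = 3 in each group for all 5 genes). In all 5 genes the 3 arrays of the cross lay outside the range of the 3 control arrays. The genes were picked from these same values, so this separation is no further support.

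None of these passed the test fixed before the data were examined. With limma, a constant prior variance and Benjamini-Hochberg adjustment over all probe sets, 0 of 18769 probe sets and 0 genes passed an adjusted p of 0.05, and the smallest adjusted p, 0.0762, was shared by 16 probe sets. At an unadjusted p under 0.05 there were 2070 probe sets, where 938 would be expected by chance, of which 539 were higher and 1531 lower in the cross, in 1260 genes in all. The other 3 against 3 groupings of the 6 arrays gave 554 to 1990 such probe sets, so the real count was close to the highest of them. Quantile scaling changed this split to 800 higher and 1198 lower, and median centring to 628 higher and 1161 lower. The 3 arrays of one group all lay above the 3 of the other in 3478 probe sets, or 18.5%, where chance gives 10%. The spread between arrays fell with signal, from a median residual SD of 0.94 on the log2 scale in the dimmest 33.3% of probe sets to 0.28 in the middle 33.3% and 0.16 in the brightest 33.3%.

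Among the other fits set out beforehand, the following made calls. With a limma prior variance that followed the signal (trended and robust, called the trended fit from here on), 147 probe sets passed, 58 higher and 89 lower, in 104 genes, of which 40 rose and 64 fell. With the dimmest 33.3% of probe sets left out and a constant prior (the brighter-probe fit), 112 of 12512 probe sets passed, 37 higher and 75 lower, in 72 genes. The fits shared 88 probe sets and 54 genes. A test of each probe set with its own unequal group variances, with the same adjustment, called 1. Leaving out single arrays moved the count of the trended fit widely, to 7 without control replicate 1, 20 without control replicate 2, 225 without control replicate 3, 11 without overexpression replicate 1 and 96 without overexpression replicate 3. Genes are described below as having risen or fallen only where they passed in the trended fit, a choice made after the counts were seen.

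**Figure D1:**
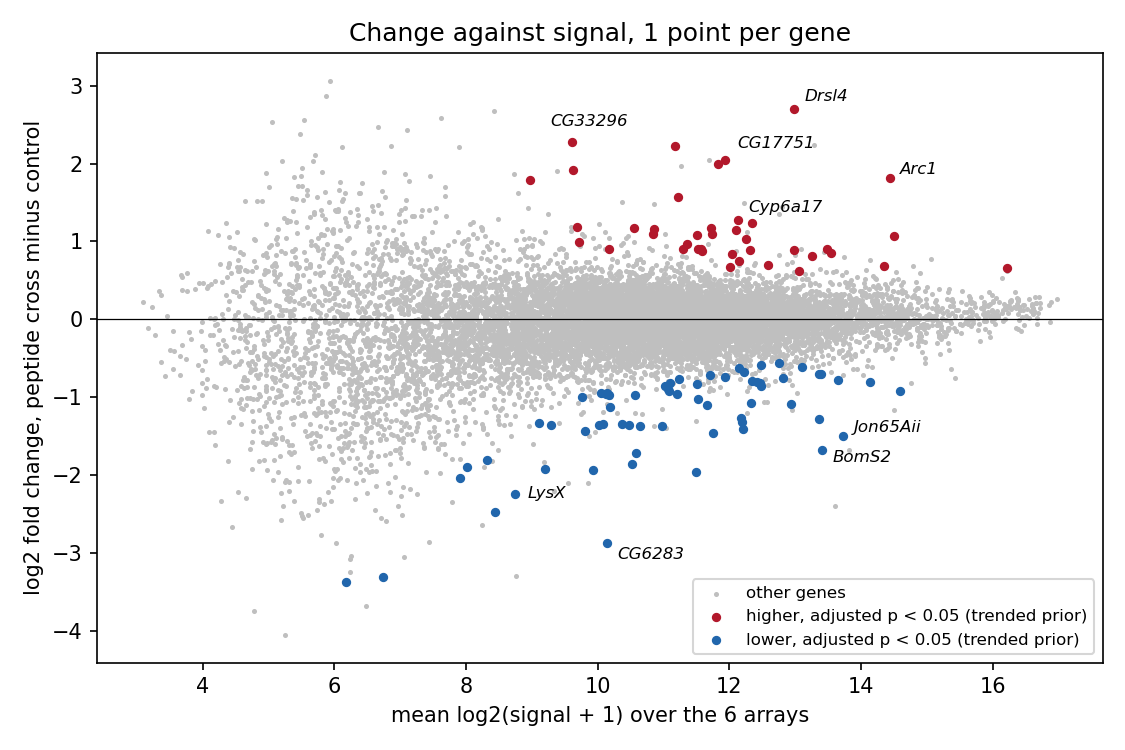
Log2 fold change (cross minus control, y axis) against mean log2(signal + 1) over the 6 arrays (x axis), 1 point per gene. Coloured points are the 104 genes past an adjusted p of 0.05 in the trended fit, 40 higher (red) and 64 lower (blue). The scatter of the other genes widens towards low signals.

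In the trended fit, the genes that rose most after Drsl4 were CG33296 (4.83-fold), CG18179 (4.67-fold), CG17751, CG10725 (3.98-fold), Alms1a (3.76-fold), Arc1 and CG42254 (3.44-fold). They were followed by CG11598 (2.96-fold), Cyp6a17 (2.41-fold), CG5676 (2.36-fold) and CG2993 (2.27-fold). The adjusted p of CG17751 and of Arc1 was 0.000638 in the trended fit and ranged from that value to 0.461 over the 13 alternatives, in 2 of which each passed. For CG6283 the corresponding values were 0.00204 and 0.00204 to 0.461, also with 2 passing. Among genes that fell, CG34214 and bard lay within the background range in the cross. They fell at least 2.10-fold and at least 3.05-fold, so their rank is not known. Among the others CG6283 fell most, followed by Srg2 (5.58-fold lower), LysX (4.73-fold), beat-VII (4.10-fold), CG4830 (3.88-fold) and alpha-Est2 (3.84-fold). Then came CG3397 (3.80-fold), CG13325 (3.73-fold), CG7900 and the glutamate receptor gene KaiR1D (3.49-fold). Log2 fold changes kept their sign in all alternatives, and that of Drsl4 ranged from 2.32 to 3.07. Among genes with the smallest p in the fixed test, Ir93a, spok, scw and CG12964 were dim. The signal of spok lay in the background range in both groups. That of Ir93a did so in the control with 108 ± 18.9 in the cross, and those of scw and CG12964 did so in the cross, at least 1.05-fold and 1.25-fold below the control. These 4 genes did not pass in the trended fit.

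The list of antimicrobial peptide genes had 21 members, of which 13 had a probe set annotated to that gene alone; the others, among them attacin and cecropin genes, were not analysed here. The 13 showed no common shift, with 6 higher and 7 lower, a median log2 fold change of -0.08 and a mean of -0.03, while the set test leaned upward (camera in limma, adjusted p = 0.468). The median turned to 0.19 without the dimmest 33.3% of probe sets, 0.22 without control replicate 2, 0.10 without control replicate 3 and 0.07 without overexpression replicate 2. None passed over all genes in the fixed test. Adjusted over the list alone, 2 passed, Drsl4 at an adjusted p of 0.00938 and Drsl2 at 0.0263. Drsl4 also passed in the trended fit (adjusted p = 0.0184, with 0.0184 to 0.461 over the alternatives). Drsl2 was lower, at 472 ± 86.5 in the control and 76.7 ± 49.5 in the cross, near the background. Drs, the antifungal peptide drosomycin, had the strongest signal of the group, 39900 ± 9812 in the control and 37117 ± 3794 in the cross, with a log2 fold change of -0.08 (95% interval of the difference -0.62 to 0.46). Metchnikowin (Mtk) was at 751 ± 92.6 and 1708 ± 617 and did not pass over the list (adjusted p = 0.053). The signal of Drsl6 lay in the background range in both groups. The log2 fold changes of Drsl5, Anp and Drsl1 were 0.73, 0.46 and 0.26, and those of Def, Drsl3, CecB, AttD and DptB were -0.27, -0.39, -0.46, -0.90 and -1.04, none past a test. For DptB, at 230 ± 280 in the control and 70.8 ± 37.8 in the cross, it ranged from -1.76 to -0.03 with 1 array left out. The sign of AttD holds on the log scale only: its mean signals were 125 ± 53.2 in the control and 212 ± 316 in the cross, where 1 array was high. The driver's source gene da had a log2 fold change of 0.06 ± 0.15 (SE).

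**Figure D2:**
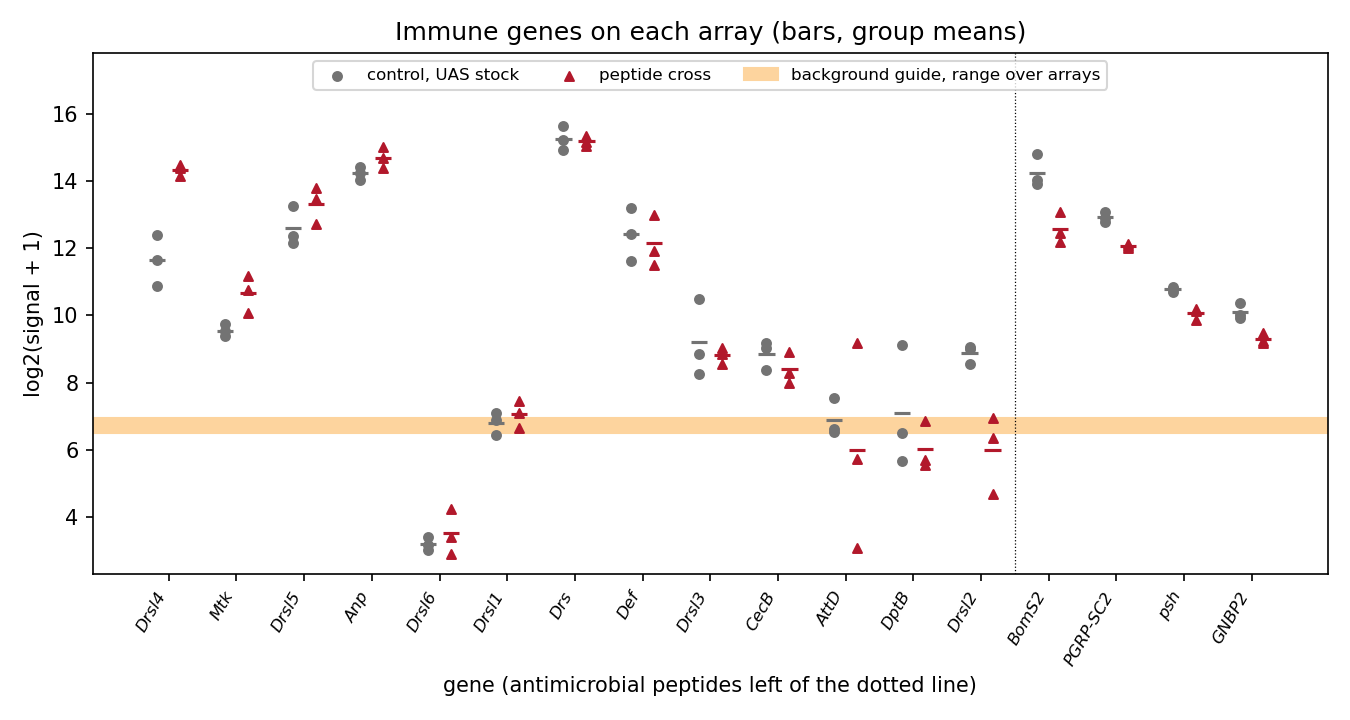
Log2(signal + 1) on each array (y axis) for the 13 measured antimicrobial peptide genes and 4 other immune genes (x axis), with control arrays as grey circles, arrays of the cross as red triangles and group means as bars. Drsl4 lies apart between the groups, the points of Drs overlap, and BomS2, PGRP-SC2, psh and GNBP2 are lower in all 3 arrays of the cross. The band is the range over arrays of the background guide.

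Among other immune-induced secreted peptides, 6 of 14 were higher and 8 lower (median log2 fold change -0.06, which became 0.02 with quantile scaling, camera adjusted p = 0.869). With 1 array left out this median ranged from -0.21 without control replicate 3 to 0.10 without control replicate 2. BomS2, a Bomanin induced by Toll signalling, fell 3.19-fold, from 20212 ± 7169 to 6295 ± 2051 (trended fit adjusted p = 0.03, list-alone adjusted p = 0.0484, and 0.03 to 0.473 over the alternatives). BomS4 was 1.30-fold higher without passing. Of 29 genes of recognition and Toll or Imd signalling, 14 were higher and 15 lower (median -0.07, camera adjusted p = 0.509), and 3 passed when adjusted over the list alone, each lower in the cross. PGRP-SC2, an amidase that degrades peptidoglycan, was 1.81-fold lower and passed in the trended fit. psh, a protease upstream of Toll, was 1.64-fold lower and GNBP2 1.74-fold lower, and neither passed in the trended fit.

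Antioxidant enzymes, which act on superoxide, peroxides and thiols, had 0 of 21 members past the test over all genes or over the list alone (median log2 fold change 0.06, 14 higher and 7 lower, camera adjusted p = 0.460). At an unadjusted p under 0.05 there were 2. These were the thioredoxin gene dhd, 1.54-fold higher, and Prx6c, 1.67-fold higher. Glutathione S-transferases moved in both directions, 18 of 35 higher and 17 lower (median 0.03, mean 0.02, set test leaning downward, camera adjusted p = 0.932). GstT3 fell 1.54-fold in the trended fit and GstE5 was 1.60-fold lower without passing. GstO2 did not pass by the probe set that stood for it. Another GstO2 probe set fell from 2397 ± 51.4 to 752 ± 162 (3.23-fold, trended fit adjusted p = 0.00687). Of 85 cytochrome P450 genes, 38 were higher and 47 lower (median -0.05, 0.0037 with quantile scaling, camera adjusted p = 0.309). Adjusted over the list alone, 11 passed, 2 higher and 9 lower, the latter with spok, whose signal lay in the background range in both groups, and 6 passed in the trended fit, 1 higher and 5 lower. Cyp6a23 fell 2.75-fold, Cyp6a8 fell 2.59-fold and Cyp4p1 fell 2.50-fold, whereas Cyp6a17 rose 2.41-fold.

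Digestive proteases, carbohydrases and lysozymes were lower in the cross as a group. Of 46 members, 39 were lower, with a median log2 fold change of -0.34 (camera with a preset correlation, adjusted p = 0.000123; adjusted p = 0.783 with an estimated correlation). Over the list alone 7 passed, 5 lower and 2 higher. Jon65Aii fell 2.83-fold, from 22989 ± 3032 to 8195 ± 1745, LysX fell 4.73-fold, Ser6 fell 2.59-fold and the maltase gene Mal-A2 fell 2.56-fold in the trended fit. Jon44E and Ser12, also serine proteases, rose 2.14-fold and 2.26-fold.

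Ribosomal protein genes were slightly higher. Of 40 cytosolic ribosomal proteins, 38 were higher (median log2 fold change 0.17, adjusted p = 5.49e-05), and of 69 mitochondrial ribosomal proteins, 60 were higher (median 0.13, adjusted p = 5.49e-05). With an estimated correlation the adjusted p was 0.783 for both, and the cytosolic list lost its call with quantile scaling (median 0.06, adjusted p = 0.188). Without overexpression replicate 3 the median of the cytosolic list was 0.09 (adjusted p = 0.0188). That of the mitochondrial list was 0.08 without overexpression replicate 1 (adjusted p = 0.00359) and 0.20 without overexpression replicate 2 (adjusted p = 1.58e-10). No single cytosolic member passed a test, RpLP2 being 1.22-fold and RpL32 1.19-fold higher. mRpL48 rose 1.86-fold in the trended fit and mRpL54 was 1.48-fold higher without passing.

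Of 36 testis and accessory gland genes, 33 were higher (median log2 fold change 0.26, adjusted p = 0.000382; adjusted p = 0.783 with an estimated correlation), and Dup99B, an ejaculatory duct peptide, rose 2.09-fold in the trended fit. Without overexpression replicate 2 the median of this list was -0.0043 and the adjusted p 0.484, and without control replicate 2, control replicate 3 and overexpression replicate 3 the median was 0.16, 0.41 and 0.44. Mst84Dd was 1.78-fold higher without passing. Of 24 egg and yolk genes, 19 were lower (median -0.35) and the list did not pass (adjusted p = 0.122; adjusted p = 0.908 with an estimated correlation), although it did with quantile scaling (adjusted p = 0.00872). With 1 array left out, the median of the egg and yolk list ranged from -0.71 without overexpression replicate 3 (adjusted p = 3.5e-07) to -0.0066 without overexpression replicate 2 (adjusted p = 0.997), and it was -0.06 without control replicate 1 (adjusted p = 0.416) and -0.48 without control replicate 2 (adjusted p = 0.0195). Its members with the smallest p were vas, 1.54-fold lower, and the chorion gene Cp18, at 28467 ± 1250 in the control and 9128 ± 11073 in the cross. Every sample held equal numbers of males and females by the labels. Haemocyte and fat body genes were lower in 19 of 22 cases (median -0.33, adjusted p = 0.0658), with Pxn 1.88-fold and srp 1.42-fold lower. That list passed with quantile scaling (adjusted p = 0.0312), median centring (0.0404), the trended prior (0.0225) and the mean of the probe sets of a gene (0.0481), and did not with an estimated correlation (adjusted p = 0.783). Its median was -0.14 without control replicate 2 (adjusted p = 0.378) and -0.17 without overexpression replicate 1 (adjusted p = 0.263), and it passed without control replicate 3 (adjusted p = 0.000294) and without overexpression replicate 3 (adjusted p = 0.0393).

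**Figure D3:**
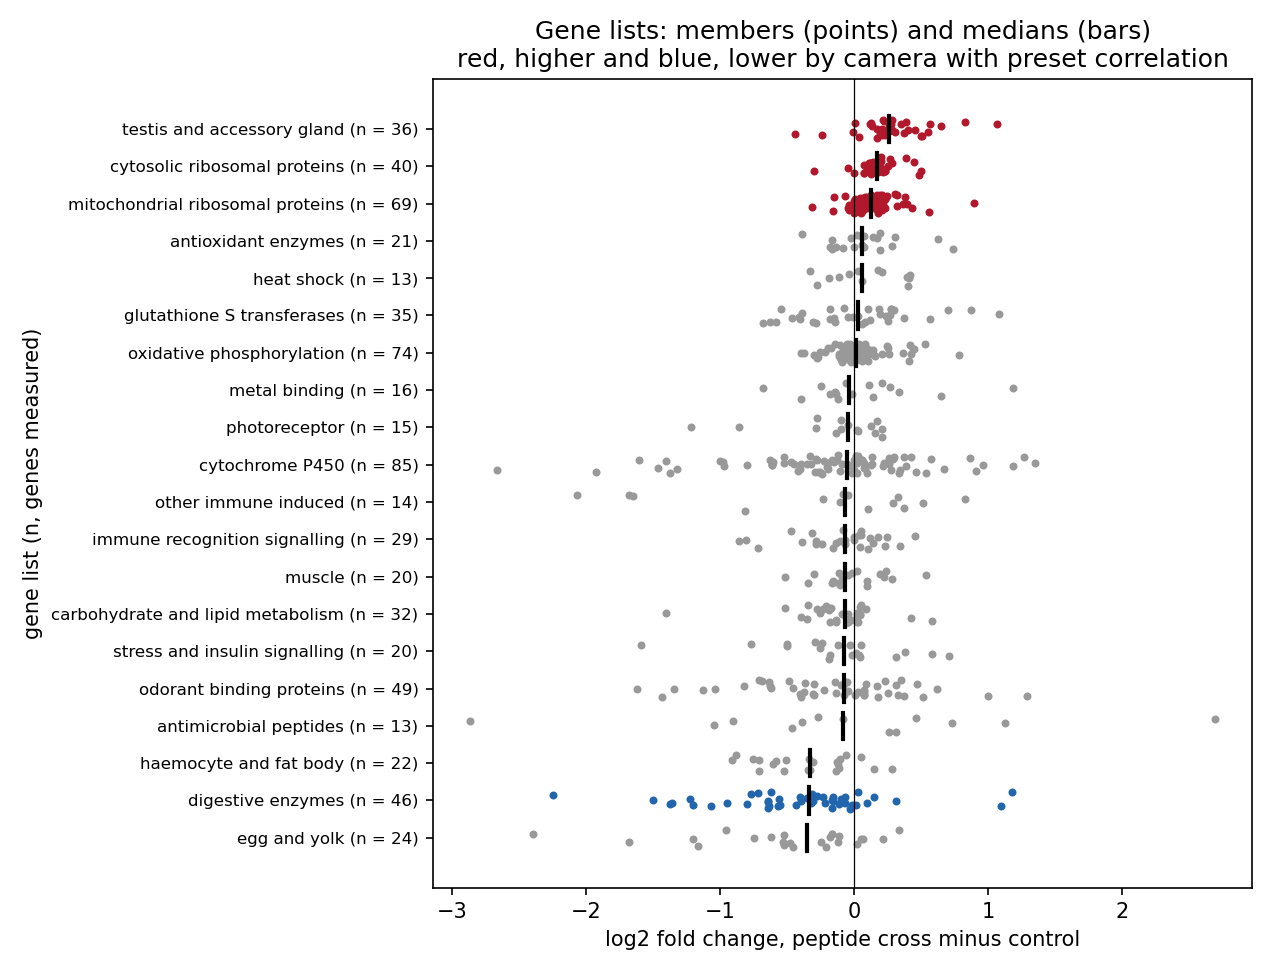
Log2 fold change (x axis, cross minus control) of the measured members of each of the 20 gene lists (y axis, points) with list medians as bars. Red lists were higher and the blue list lower by camera with a preset correlation. The 3 red lists have medians of 0.13 to 0.26 and the blue list a median of -0.34. None of the 4 passed with an estimated correlation.

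In the other lists no member passed the trended fit or the test over the list alone by the probe set that stood for it. Another probe set of RFeSP, of the respiratory chain list, fell from 6242 ± 1242 to 2758 ± 500 (2.26-fold, trended fit adjusted p = 0.028). Of the 26 heat shock genes listed, 13 had a probe set annotated to that gene alone. A probe set shared by Hsp70Aa and Hsp70Ab passed in the trended fit and is described below. The median log2 fold change was 0.06 for heat shock proteins (13 genes, adjusted p = 0.460, Hsp68 1.33-fold higher and Hsp60A 1.26-fold lower) and 0.01 for respiratory chain subunits (74 genes, adjusted p = 0.468, -0.05 with quantile scaling, ND-20L and ND-24L 1.72-fold and 1.44-fold higher). The respiratory chain list passed upward without overexpression replicate 1 (median 0.13, adjusted p = 0.00478; adjusted p = 0.956 with all arrays and an estimated correlation), and its median was -0.14 without control replicate 3 and -0.12 without overexpression replicate 3. The median was -0.05 for photoreceptor genes (15 genes, adjusted p = 0.791, 0.0041 with median centring, eys 2.32-fold and rdgA 1.81-fold lower) and -0.07 for odorant-binding proteins (49 genes, adjusted p = 0.579, lush 1.54-fold lower and Obp56a 2.00-fold higher). Muscle genes had a median of -0.07 (20 genes, adjusted p = 0.932, sls 1.43-fold lower and Mlc2 1.45-fold higher) and metal-handling genes of -0.04 (16 genes, adjusted p = 0.869, Mvl 1.26-fold higher and ATP7 1.32-fold lower), both with the set test leaning upward against the sign of the median. Stress and insulin signalling genes had a median of -0.07 (20 genes, adjusted p = 0.538, dome 1.42-fold and hep 1.41-fold lower). Carbohydrate and lipid metabolism genes had a median of -0.07 (32 genes, adjusted p = 0.363, tobi 2.64-fold lower and Lip4 higher by 0.58 on the log2 scale), and that list passed with quantile scaling (adjusted p = 0.0312; adjusted p = 0.908 with an estimated correlation). It also passed without control replicate 3 (median -0.22, adjusted p = 0.00469) and without overexpression replicate 3 (median -0.18, adjusted p = 0.0393), and its median was -0.0013 without overexpression replicate 1 (adjusted p = 0.905).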

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

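The neighbour count and the counts over other splits of the arrays were fixed before their results were seen, and the tests of single-copy alleles, gut share, immune induction and transgene signal were chosen after.

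The comparison does not use the 183 control probe sets. Of these, 2 were higher in every array of the cross, at least 2-fold in the mean and above the background guide on each of those arrays. Picking probe sets for this separation fixes the exact permutation p at 0.1, so that p-value is no test of them. The control probe set K01486-1, whose target is not named in the tables used here, had a signal of 179 ± 52.5 in the control and 1035 ± 164 in the cross (SD, n = 3 each), 5.79-fold higher (exact permutation test, 2-sided p = 0.1, the smallest that 3 against 3 arrays allow). The probe set for the middle of 18S ribosomal RNA had 1135 ± 403 and 5259 ± 4324, 4.64-fold higher (exact p = 0.1), with 1677, 4037 and 10063 on the 3 arrays of the cross and 899, 1599.5 and 905 on those of the control. Its 3' probe set was 1.45-fold higher (exact p = 0.2). Its 5' probe set was 3.62-fold higher (exact p = 0.3, with 112 on 1 array of the cross, inside the control range of 92.3 to 220.3). The 3' to 5' ratio of actin was 1.48 ± 0.049 and 1.56 ± 0.116. The Escherichia coli BioB spike, a mean of 3 control probe sets, was 2491 ± 327 and 3597 ± 1163 (exact p = 0.3). On the arrays of the cross it read 2364, 3752 and 4674, rising in the same order as the middle 18S probe set. On those of the control it read 2823, 2170 and 2481, not in that order. Differences between single arrays as the source of the 18S values were not tested.

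The fixed test called 0 probe sets in the real grouping and 0 at most in the other splits of the 6 arrays, so that all 10 splits gave as many. The trended fit called 147 probe sets in the real grouping and 2 at most in the others, so that 1 of 10 splits, the real one, gave as many. At an unadjusted p under 0.05, the fixed test had 2070 probe sets in the real grouping, 1990 in the split of control replicates 1 and 2 with overexpression replicate 3 against the rest, and 1485 in that of control replicates 1 and 2 with overexpression replicate 2, so that these splits of mixed groups also part the arrays. With 10 splits the share cannot fall below 10%, too few for a share under 0.05.

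In the trended fit, 64 of the 104 called genes were lower in the cross. If the cross, with 1 parent from the driver stock, had only lost working or probe-matching alleles from that parent, autosomal genes would keep 1 working copy and fall by no more than 1 on the log2 scale. In the trended fit, however, 15 of the 54 measured autosomal genes that fell had an upper 95% limit below -1 on the log2 scale, among them CG6283 (upper limit -2.34) and LysX (upper limit -1.47). The genes were chosen by the same fit, and the limits are not adjusted for that choice. Those of Cyp4p1, BomS2 and Cyp6a23 (-1.06, -1.07 and -1.08) lay close to -1. The bound also assumes a signal proportional to the transcript. On that assumption the values argue against single-copy alleles as the sole cause of the falls. They do not settle the 15 genes one by one and leave the others open. A few linked chromosome segments carried over from 1 parent would put called genes next to each other. Of the 103 called genes with a place in the gene order, 2, Cyp6a17 and Cyp6a23, neighboured another called gene. The median in 10000 random gene sets was also 2 (one-sided permutation p = 0.583). The count covers directly adjacent genes only and misses called genes a few places apart in 1 segment, so such segments stay open. Other differences in genetic background between the cross and the uncrossed line, and an effect of the peptide, remain open, untested, since no driver-only flies were analysed here.

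The digestive genes were lower as a group with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.783). A smaller share of gut tissue in the cross would lower all of them alike, whereas 2 of the 7 members that passed over the list alone, Jon44E (log2 fold change 1.10, 95% interval 0.59 to 1.60) and Ser12 (1.17, 0.56 to 1.79), were higher. These values argue against gut share as the sole cause of the change in those 2 genes. For the 39 members that were lower, a smaller gut share stays open. An effect of diet, of the genetic background or of the peptide was not tested.

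Drsl4 stood out among the peptide genes. A general induction of immune peptides would raise the other genes of this kind. Of 26 others measured, 1 had a lower 95% limit above 0 (Mtk) and 2 had an upper limit below 0 (Drsl2 and BomS2). These 2 argue against an induction that takes in all the measured genes. Wide intervals, such as those of Drsl5 (-0.30 to 1.77) and Def (-1.65 to 1.12), still allow a rise of some others, whereas that of Drs (-0.62 to 0.46) allows little. Only 13 of the 21 antimicrobial peptide genes listed were measured, so an induction of the others is not excluded. Signal from the transgene itself may account for Drsl4 if the construct encodes it or a sequence its probe set reads. The next highest rise among the peptide genes was a log2 fold change of 1.12 (Mtk), and since the labels do not name the peptide this explanation stays open. A regulated response of Drsl4 to the peptide also stays open and was not tested.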

How the results depend on the processing

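The count of the trended fit under its own alternatives was computed after seeing the data. The fixed test called 0 probe sets and 0 genes with every array left out in turn (range 0 to 0), with quantile scaling, median centring, a pseudocount of 16 and the other settings fixed beforehand, except 112 probe sets and 72 genes without the dimmest 33.3%, 147 probe sets and 104 genes with the trended and robust prior, and 1 probe set with unequal group variances. The trended fit called 146 probe sets with quantile scaling, 150 with median centring, 147 with a pseudocount of 16, 179 without the dimmest 33.3% and 129 without robust estimation, which share 129, 120, 146, 144 and 128 of its 147 calls. Leaving out 1 array gave 7 to 225 calls, with the log2 fold changes of all 147 keeping their sign. The cause of these differences was not tested. Of the 20 lists, 4 passed in the fixed setting, 0 with an estimated correlation and 3 to 7 with 1 array left out. Among named genes, changes of sign came from leaving out 1 array: Drsl3 ranged from -0.86 to 0.27, AttD from -2.49 to 0.55, Def from -0.69 to 0.13, Drs from -0.24 to 0.10, and da from -0.0184 to 0.14. List medians changed sign in 10 of the 20 lists, 7 of them in a setting that keeps all arrays and 9 with 1 array left out. Of the 4 lists that passed, 1 was among these, the testis list. The muscle list, at -0.40 to 0.13 with 1 array left out, passed downward without control replicate 3 (adjusted p = 0.00471). Low signal limits the fit: the median residual SD was 0.94 in the dimmest 33.3% and 0.16 in the brightest 33.3%, and the median log2 fold change was -0.24 and 0.02.

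The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered samples over all probe sets correlated at -0.0225, 0.00066 and -0.0972 and gave no sign of pairs. Dim probe sets, which spread most, weigh heavily in these values, so a shared effect in brighter ones is not excluded. With the number as a block, the fixed test called 0 probe sets and 0 genes, the trended fit 8 probe sets, and 6 lists passed, the egg and yolk list and the haemocyte and fat body list (adjusted p = 0.04997 each) besides the 4.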

Other observations

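Of the 147 probe sets called in the trended fit, 31 had no single gene symbol. The largest rises among them were 1630954_at, from 94.8 ± 74.7 to 962 ± 256 (11.8-fold), and 1626516_at, from 64.8 ± 17.9, within the background, to 644 ± 258 (at least 5.66-fold). The control arrays of 1630954_at read 45, 58.6 and 181, and only the last lay above the background guide, so its fold is uncertain. The largest falls were 1626319_a_at, from 2754 ± 395 to 403 ± 38.9 (6.79-fold), and 1624819_s_at, from 7548 ± 1809 to 1130 ± 155 (6.59-fold, SD, n = 3 each for all 4). These were chosen after their values were seen.

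The neighbouring P450 genes Cyp6a17 and Cyp6a23 went in opposite directions, with log2 fold changes of 1.27 ± 0.17 and -1.46 ± 0.20 (SE) and with all 3 arrays of the cross outside the range of the control in each. A probe set annotated to both Hsp70Aa and Hsp70Ab had signals of 501 ± 75.3 in the control and 1218 ± 182 in the cross (2.43-fold, trended fit adjusted p = 0.0346), while the brightest probe set annotated to the 4 Hsp70B genes alone had 274 ± 50.9 and 332 ± 71.1 (adjusted p = 0.733). A brighter probe set annotated to Hsp70Bb, Hsp70Bc and CG31343 had 15400 ± 845 and 11026 ± 2613, lower in the cross (adjusted p = 0.222). A dim probe set annotated to Hsp70Bb and Hsp70Bc had 28.8 ± 17.6, within the background, and 122 ± 41.2 (adjusted p = 0.261). The difference between these probe sets was not tested.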
